A study of Homo sapiens with 5 samples.

How the data were processed

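Total RNA from 5 samples of MDA-MB-453 cells was measured with the QuantSeq 3' mRNA kit in its forward version, in which cDNA is primed with oligo(dT) and the second strand with random primers, per the labels' protocols. The RNA input was 250 ng, with an average integrity number of 9.6 (range 9.4 to 9.8), per the labels. Cas9 was induced with doxycycline (DOX) at 1 µg/ml over 3 days. The colonies then went through cycles of 3 days in 100 nM rigosertib and 4 days without it over 4 to 5 weeks, and through 10 more days of growth, per the labels. Groups were taken from the sample titles: 1 parental library without DOX, 1 parental library with DOX, and the 3 resistant colonies 4, 6 and 8.

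The deposited table holds raw counts per gene, whole numbers for 61544 genes in 5 columns, made by the authors from the reads. The genome build was GRCh38.p13, per the submitters' processing notes. The aligner, the counting tool, the annotation and the strand setting are not given in the sources used here. Reads of a 3' kit fall near the polyadenylation site, so counts do not grow with transcript length, they do not report guides or edits, and a gene whose 3' end resembles that of another gene can lose or gain reads. All columns were mapped to a sample by name. No row lacked a gene identifier. Symbols were taken from the table. Coordinates, exon overlaps and transcript sequences were taken from GENCODE 29 on GRCh38, which matched 58342 of the identifiers and 99.87% of the counts. For genes with at least 100 counts in 1 library, the share of 31-base words in the last 300 bases of their transcripts that also occur in transcripts of another gene was computed.

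Total counts ran from 5698910 to 6726953 per library. Values of a few CPM rest on few counts and carry large counting errors. Counting errors do not cover the differences between cultures, and reads without molecular identifiers are not independent molecules.

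The design, the gene lists and the rule for naming genes were fixed before the data were examined. The comparison took the 3 colonies against the 2 parental libraries together, because neither parental treatment had a replicate. Any effect of DOX is therefore part of the spread within the parental arm. The 3 colonies had DOX as well, so a lasting effect of DOX would also enter the difference between the arms. Genes were filtered with filterByExpr, leaving 12704, counts were scaled by TMM, and edgeR 4.0.16 (R 4.3.3) was used for a two-sided quasi-likelihood test with robust dispersion estimates, with its newer method set explicitly. P-values were adjusted by the Benjamini-Hochberg method and genes passed under 0.05. The fit had 3 residual degrees of freedom and a common biological coefficient of variation of 0.321. CPM values use the total counts as deposited. Of 53 gene lists, the 49 with at least 5 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and adjusted over the lists. The correlation estimated per list and the rotation test fry were the alternatives.

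The parental library with DOX was compared with that without DOX by log2 ratios with a prior of 2 counts, over genes with at least 100 counts in 1 of them, without a test. List medians were placed among 10000 random lists of the same size matched on mean expression. Where a library had 0 counts, 3 counts served as the limit.

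The rule named WNK1 to WNK4 and PLK1 whatever their values. It also named the 10 genes per direction with the largest log2 fold change among those past the threshold with an average log2 CPM of at least 3 and all 3 colonies beyond both parental libraries, up to 4 members past the threshold per list, the 5 largest ratios per direction between the parental libraries, and the 3 genes per direction farthest beyond the other 4 libraries in each colony. Genes without an approved symbol, pseudogenes, XIST, TSIX and Y-linked genes were left out of the named genes of the main comparison. Since 0 genes passed with edgeR, the part on the largest changes was applied to the DESeq2 1.42.0 calls, where 16 genes at higher and 22 at lower levels met it, and list members were taken by lowest unadjusted p. Both choices were made after the values were seen.

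The alternatives were median-ratio size factors, library size only, no filter, a filter of 50 counts in 2 libraries, DESeq2 with its own filtering in place of filterByExpr, limma-voom, the older quasi-likelihood method, a fit with 3 groups, a test against a 1.5-fold change, and leaving out each library in turn. Leaving out mitochondrially encoded genes with MALAT1, leaving out 1434 genes with shared 3' ends, the list test in the 3-group fit, leaving out each library with the genes tested in all 5 libraries, DESeq2 on the genes edgeR tested, and a test of DOX in that fit were added after seeing the data. The gene test and the list test were tested on simulated data with the means, depths and spread of these libraries and with genes changed 2-fold (67), 4-fold (67) and 8-fold (66) among 12704. For resistant against parental, edgeR recovered 17.9% of the genes changed 2-fold, 62.7% of those changed 4-fold and 95.5% of those changed 8-fold, with 4 false calls. DESeq2 recovered 20.9%, 62.7% and 90.9%, with 12 false calls. Camera found 20 of 20 lists shifted by 0.6 on the log2 scale and 0 unshifted ones. Genes were simulated independently of each other, with a spread that followed the trend over expression. The simulation therefore does not cover genes with a wider spread than the trend. Nor does it cover lists whose members move together, such as the mitochondrially encoded mRNAs with an estimated correlation of 0.684. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.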

Results

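Gene expression was measured by sequencing of transcript 3' ends in MDA-MB-453 cells, an established human breast cancer line, that carried a library of CRISPR guide RNAs and a Cas9 switched on by doxycycline (DOX). The 5 libraries came from 1 parental sample without DOX, 1 parental sample with DOX, and 3 colonies, numbered 4, 6 and 8, that had survived repeated exposure to 100 nM rigosertib. Rigosertib is an anticancer compound for which Polo-like kinase, RAS effectors and microtubules have been named as targets. The comparison asked how the transcriptome of the resistant colonies differed from that of the parental cells, in a screen whose title names depletion of WNK1. Total counts were 6382588 in the parental library without DOX, 5698910 in the parental DOX library, and 6532540, 6236877 and 6726953 in colonies 4, 6 and 8. The colonies were labelled as separate and had been given DOX for 3 days, like the parental DOX library. Only for the colonies do the labels give 4 to 5 weeks of rigosertib cycles and 10 days of growth afterwards. No colony without rigosertib was among the 5 libraries. Resistance therefore cannot be told apart from drug exposure, time in culture or growth as a colony. Nothing in the labels says that the parental libraries came from separate cultures, and these differed in DOX, so p-values measure only the spread between these samples, which may in part be technical.

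WNK1, a kinase that activates SPAK and OSR1 and through them controls cation-chloride cotransporters, was lower in each of the 3 colonies than in both parental libraries. The gene (ENSG00000060237.19) lies on the plus strand of chromosome 12 from 752593 to 911452 in GRCh38. Its level was 63.2, 99.9 and 46.1 counts per 1000000 counts of the library (CPM) in colonies 4, 6 and 8, against 227.5 CPM in the parental library without DOX and 501.5 CPM in the parental DOX library. These values rest on 413, 623 and 310 counts in the colonies and on 1452 and 2858 counts in the parental libraries. The log2 fold change of resistant against parental was -2.50 with a standard error (SE) of 0.431. WNK1 had the lowest p of all genes by DESeq2 (log2 fold change -2.45, SE 0.416, adjusted p = 4.77e-05), but its adjusted p by edgeR was 0.474. Over the settings tried besides DESeq2 and the test against a 1.5-fold change (0 genes called), its adjusted p ranged from 0.0703 to 0.782. By edgeR its log2 fold change was -1.72 against the parental library without DOX alone and -2.94 against the parental DOX library alone. A 3' tag reads neither guides nor edited alleles, so it does not check the editing of WNK1.

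The paralogs WNK2, WNK3 and WNK4 were sparse in every library, with at most 7.37 CPM for WNK2, 1.38 CPM for WNK3 and 3.57 CPM for WNK4. PLK1, the Polo-like kinase named as a target of rigosertib, had 13.6, 11.1 and 20.96 CPM in colonies 4, 6 and 8 and 19.1 and 12.8 CPM in the parental libraries without and with DOX. Its log2 fold change was -0.17 (SE 0.359, edgeR, adjusted p = 0.907), and it was 0.14 when the parental library without DOX was left out. In the list of WNK, SPAK and OSR1 pathway genes and cotransporters, the median log2 fold change of the 18 tested members was -0.15 (limma's camera, adjusted p = 0.278). Adjusted over the list alone, 1 member passed with edgeR, WNK1, and 2 with DESeq2, WNK1 and NRBP2, both lower. Over all genes tested, 0 members passed with edgeR and 1 with DESeq2, again WNK1.

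**Figure D1:**
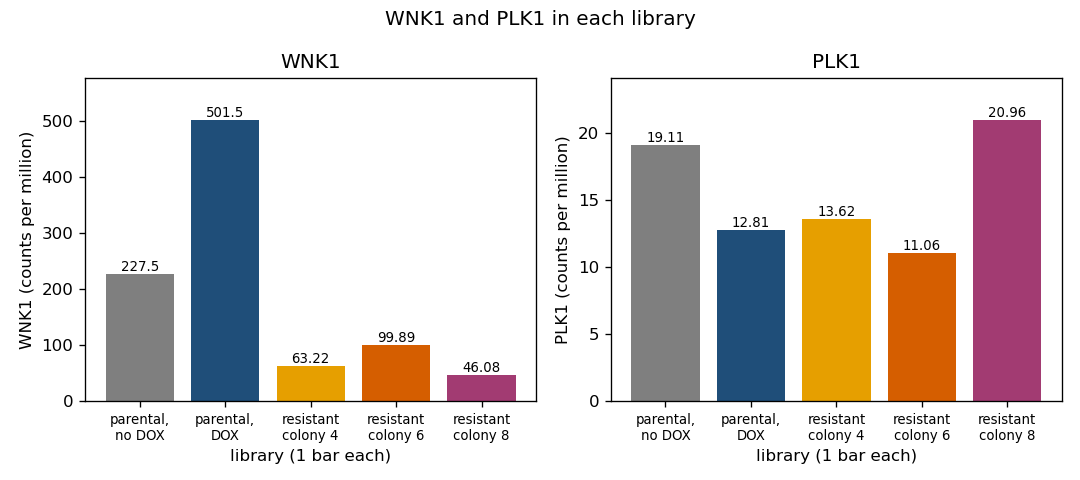
WNK1 (left) and PLK1 (right) in CPM, 1 bar per library, with no error bars because each bar is a single library. The 3 resistant colonies sit between 46.1 and 99.9 CPM for WNK1, below both parental libraries at 227.5 and 501.5 CPM, while the PLK1 bars of the colonies and the parental libraries overlap.

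Among the genes at higher levels in all 3 colonies than in both parental libraries were TAT, DDC, DHRS3, ST6GAL1 and CHST1. TAT, tyrosine aminotransferase, stood at 25.3, 3.21 and 14.3 CPM in colonies 4, 6 and 8 and at 1.57 and 1.40 CPM in the parental libraries without and with DOX (DESeq2, log2 fold change 3.20, SE 0.731). DDC, aromatic amino acid decarboxylase, stood at 39.6, 18.8 and 56.3 CPM against 10.5 and 6.32 CPM. DHRS3, a retinaldehyde reductase, averaged 16.5 ± 10.5 CPM (mean ± SD, n = 3 colonies) against 1.57 and 2.98 CPM. The sialyltransferase ST6GAL1 averaged 52.7 ± 34.0 CPM against 10.5 and 9.83 CPM, and the sulfotransferase CHST1 averaged 152 ± 60.3 CPM against 23.5 and 65.8 CPM. DOCK2, an exchange factor for the small GTPase RAC, had 15.0 ± 3.07 CPM against 3.13 and 2.46 CPM, and the transcription elongation factor TCEA3 had 18.6 ± 5.29 CPM against 4.54 and 2.81 CPM. GASK1B averaged 61.1 ± 41.4 CPM against 12.2 and 8.60 CPM, AFF3, a nuclear regulator of transcription, 16.6 ± 14.2 CPM against 0.940 and 3.33 CPM, and CALML5, a calmodulin-like protein of the epidermis, 187 ± 102 CPM against 66.3 and 44.8 CPM, with wide differences between the colonies. Colony 6 was the lowest of the colonies for TAT, DDC, DHRS3, ST6GAL1, GASK1B, AFF3 and CALML5, and for DHRS3 it had 4.33 CPM where colonies 4 and 8 had 22.2 and 22.9 CPM. By edgeR the log2 fold changes of AFF3, DHRS3 and CHST1 were 2.84, 2.74 and 1.62, and they were 4.07, 3.34 and 2.64 without the parental DOX library. That of AFF3 was 1.94 without colony 8, and that of TAT was 3.14 with all libraries and 2.40 without colony 4. GASK1B passed without colony 6 (2.84, edgeR, adjusted p = 0.0494).

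Genes at lower levels in all 3 colonies than in both parental libraries included WNK1, a stress cytokine, a chloride channel and a nuclear long non-coding RNA. GDF15, a stress-induced cytokine and p53 target, had 21.3 ± 4.55 CPM (n = 3 colonies) against 98.2 and 61.9 CPM in the parental libraries without and with DOX (DESeq2, log2 fold change -1.96, SE 0.354, adjusted p = 0.000182). Over the settings tried besides DESeq2 and the test against a 1.5-fold change (0 genes called), the adjusted p of GDF15 ran from 0.00887 to 0.662. ANO1, a calcium-activated chloride channel, had 15.6 ± 6.21 CPM against 42.9 and 63.5 CPM. TRIM29, a gene of basal epithelium, had 5.03 ± 0.114 CPM against 24.3 and 10.7 CPM. IER5, an immediate-early gene, had 23.6 ± 6.48 CPM against 156 and 33.5 CPM. CAPN8, a calpain protease, had 18.7 ± 8.93 CPM against 93.7 and 39.7 CPM, SYTL2, a synaptotagmin-like protein of vesicle traffic, 4.52 ± 2.42 CPM against 30.7 and 12.1 CPM, and NHS 6.51 ± 3.16 CPM against 37.6 and 13.9 CPM. NEAT1, the RNA scaffold of paraspeckles, had 484 ± 135 CPM against 1010.0 and 2319 CPM, and MALAT1, another nuclear RNA, took 0.752% to 0.916% of the counts in the colonies against 1.76% and 2.47% in the parental libraries. RPS18 was also lower in the colonies, at 7.62 ± 3.26 CPM against 15.5 and 44.6 CPM, but 40.9% of the words in its 3' end occur in another gene, so its level is uncertain. Without the parental library that had no DOX, the log2 fold changes of IER5, CAPN8, NHS, SYTL2 and TRIM29 by edgeR were -0.61, -1.19, -1.19, -1.53 and -1.19, against -2.06, -1.92, -2.06, -2.32 and -1.88 with all libraries. Without the parental DOX library those of NEAT1 and RPS18 were -1.08 and -1.06 (-1.90 and -2.10 with all libraries), and that of IER5 was -2.75 (edgeR, adjusted p = 0.0337). The parental arm of that fit is the single library with 156 CPM of IER5, and its spread comes from the colonies alone.

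**Figure D2:**
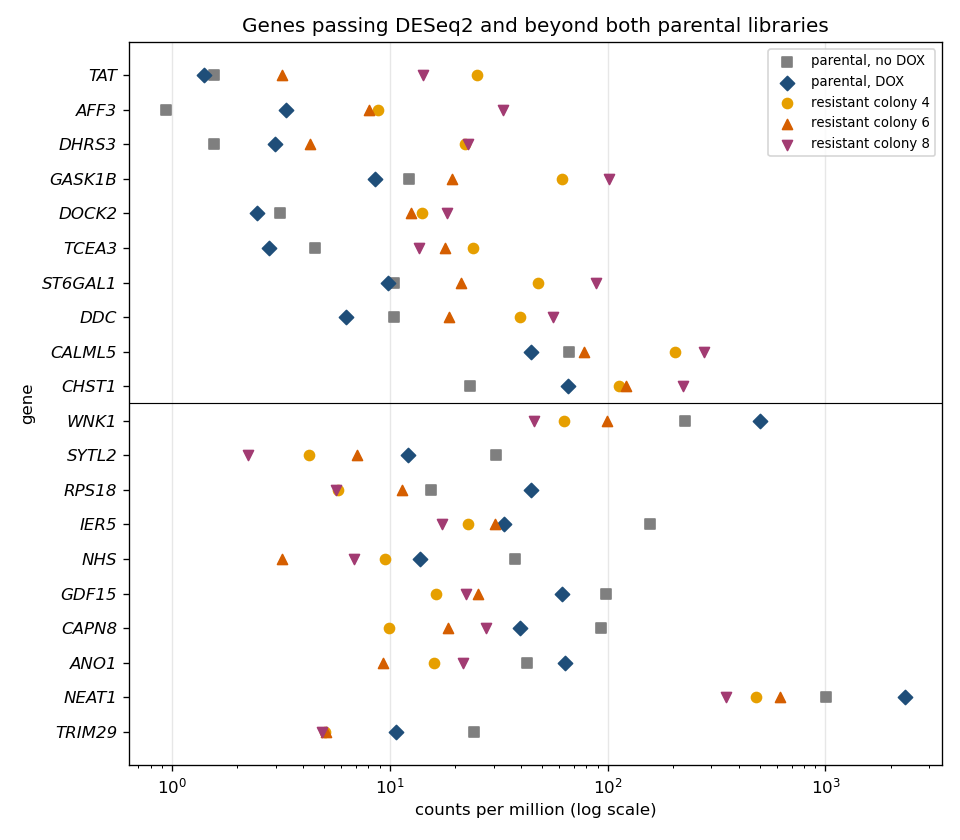
CPM on a log axis for the 20 genes named from the DESeq2 test, 1 marker per library, with the 10 genes at higher levels in the colonies above the line and the 10 at lower levels under it. All 3 colony markers of each gene lie on one side of both parental markers, as the rule for naming required, and WNK1 runs from 46.1 to 501.5 CPM.

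By edgeR's quasi-likelihood test, 0 of the 12704 genes tested passed an adjusted p of 0.05, and the lowest adjusted p was 0.474. At an unadjusted p under 0.05 edgeR gave 1029 genes, 371 higher and 658 lower in the colonies, and this split was 513 higher and 462 lower when the counts were scaled by library size only. DESeq2, run without edgeR's filter on 25291 genes, called 51 genes, 20 higher and 31 lower, and limma-voom called 0. On the 12704 genes DESeq2 also called 51, 46 of them in both runs, and CHST1 was the 1 of the 20 genes described above that it then did not call (adjusted p = 0.0709). All 49 calls of the first DESeq2 run that edgeR also tested had an unadjusted edgeR p under 0.05. The 20 genes described above were taken from the DESeq2 calls after the values had been seen, since the rule fixed for naming genes gave 0 genes with edgeR, whose adjusted p for them ran from 0.474 to 0.588. Leaving out 1 library moved the fold change of 12 of the 20 by over 1.5 times. The sign changed for 0 of them, which the naming rule all but fixed by requiring all 3 colonies beyond both parental libraries. In CPM on the total counts, without TMM scaling, all 3 colonies lay above both parental libraries in 1894 genes and below both in 1237. These are 24.6% of the genes tested, where chance gives 20%. Scaling by library size only also gave more higher than lower genes at an unadjusted p under 0.05, unlike TMM. The split of 1894 and 1237 therefore gives no direction apart from the scaling. Leaving out the parental DOX library gave 12 edgeR calls, leaving out colony 4 gave 1 and leaving out colony 6 gave 4. The 1 was YWHAE, with 484 counts in colony 4 and 1 and 11 in colonies 6 and 8 (edgeR, adjusted p = 0.00247), and the 4 were UGT2B28, UGT2B11, GASK1B and ENSG00000220130, all chosen after their values were seen. Exons of TAT, AFF3, GASK1B, DDC, CHST1, WNK1, ANO1, NEAT1 and RPS18 overlap exons of another annotated gene, and the strand setting of the counting is not given in the sources used here; the antisense gene within WNK1 had at most 4 counts in any library.

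Of 49 gene lists tested with limma's camera, 14 passed an adjusted p of 0.05 at the preset correlation of 0.01, 9 higher and 5 lower in the colonies. This balance rested on which parental library was kept, with 5 lists higher and 10 lower without the parental DOX library, and 10 higher and 2 lower without the other parental library. With the correlation estimated for each list, 0 of them passed, and the rotation test fry gave 1, the immediate-early genes. The members named below were the ones with the lowest unadjusted edgeR p, taken after their values were seen, because 0 members of any list passed over all genes tested by edgeR. Fits without 1 library were filtered anew, which changed the members of some lists, except where values are given over the genes tested with all 5 libraries, an alternative chosen after seeing the data. Without either parental library the parental arm was a single library, assumed to vary like the colonies. The parental DOX library stood apart from the other 4 libraries. It had 26.7% of its counts in mitochondrially encoded genes, against 15.6% in the parental library without DOX and 13.2%, 14.5% and 12% in colonies 4, 6 and 8, and it alone lay at 69.7 on a first principal component on which the others ran from -32.4 to 0.93.

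Immediate-early genes, which are transcribed within minutes of growth factor or stress signals, fell as a list. The median log2 fold change of its 19 tested members was -0.91, and 18 of the 19 were negative (camera, adjusted p = 6.87e-11; adjusted p = 0.223 with an estimated correlation). Adjusted over the list alone, 9 members passed with edgeR: KLF2, EGR1, JUN, KLF6, IER5, FOS, FOSB, NR4A1 and MYC. With DESeq2 8 members passed over the list alone and 3 over all genes, all lower. KLF2 had 24.5 ± 5.28 CPM in the colonies (n = 3) against 64.4 and 76.3 CPM in the parental libraries without and with DOX, EGR1 had 95.7 ± 15.3 against 172 and 309 CPM, and JUN had 102 ± 9.78 against 210 and 158 CPM. FOS averaged 10.9 ± 4.34 CPM against 20.99 and 31.8 CPM. Set against the parental library without DOX, the log2 median of this list was 0.11 in the parental DOX library, and the medians of colonies 4, 6 and 8 were -1.01, -0.86 and -0.92.

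Cholesterol biosynthesis genes, the targets of SREBP2, rose as a list in the colonies. Of 23 tested members 21 had a positive log2 fold change, with a median of 0.60 (camera, adjusted p = 3.99e-10; adjusted p = 0.471 with an estimated correlation). Adjusted over the list alone, 4 members passed with edgeR and 7 with DESeq2, all higher, and over all genes 0 and 2. INSIG1, which retains the SREBP complex in the endoplasmic reticulum, had 289 ± 55.5 CPM (n = 3) against 88.0 and 141 CPM in the parental libraries without and with DOX. The sterol oxidase MSMO1 had 130 ± 61.8 CPM against 37.0 and 46.1 CPM, squalene epoxidase SQLE had 242 ± 25.7 CPM against 112 and 124 CPM, and NSDHL had 124 ± 19.9 CPM against 73.0 and 44.4 CPM. The list of fatty-acid synthesis genes, targets of SREBP1, had a median of 0.17 and did not pass (camera, adjusted p = 0.182), except without the parental DOX library (0.47, adjusted p = 0.0102; 0.10 and adjusted p = 0.966 without the other parental library) and without colony 6 (adjusted p = 0.029, or 0.0611 over the genes tested with all 5 libraries). Set against the parental library without DOX, the cholesterol list stood at 0.30 in the parental DOX library and at 0.91, 0.59 and 0.79 in colonies 4, 6 and 8.

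Mitochondrially encoded mRNAs fell as a list and nuclear-encoded subunits of the respiratory chain rose, and both lists stood apart in the parental DOX library (1.30 and -0.69 against the parental library without DOX). The mitochondrially encoded list had a median log2 fold change of -1.0 over 13 members (camera, adjusted p = 2.43e-09; adjusted p = 0.606 with an estimated correlation). It was -0.25 against the parental library without DOX alone (adjusted p = 0.0417) and -1.51 against the parental DOX library alone. MT-ATP6, MT-ND1, MT-ND2, MT-ND6 and MT-CYB passed with edgeR when adjusted over the list alone, where DESeq2 called 11 members, all lower. MT-CYB had 2626 ± 499.9 CPM in the colonies against 3456 and 8078 CPM in the parental libraries without and with DOX. The 3' ends of MT-ATP6, MT-ND1, MT-ND2 and MT-ND6 share from 31.5% to 77.0% of their words with other annotated genes, so these levels are uncertain. The nuclear-encoded list had a median of 0.52 over 44 members, 41 of them positive (camera, adjusted p = 5.87e-09; adjusted p = 0.497 with an estimated correlation), and 0 members passed with edgeR or DESeq2 when adjusted over the list alone. Its median was 0.23 against the parental library without DOX alone and 0.90 against the parental DOX library alone. COX5B, a subunit of cytochrome c oxidase, had 437, 444 and 490 CPM in colonies 4, 6 and 8, 332 CPM in the parental library without DOX and 130 CPM in the parental DOX library.

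Cell cycle genes rose as lists in the colonies. The G1/S and DNA replication list had a median log2 fold change of 0.34, with 28 of 31 members positive (camera, adjusted p = 4.76e-05; adjusted p = 0.344 with an estimated correlation). The G2/M and mitosis list had a median of 0.30, with 29 of 33 positive (camera, adjusted p = 1.87e-05; adjusted p = 0.641 with an estimated correlation). Neither list had a member past the threshold with edgeR or DESeq2 when adjusted over the list alone. The replication factor GINS2 had 69.2 ± 11.5 CPM (n = 3) against 42.0 and 32.5 CPM in the parental libraries without and with DOX. BIRC5 (survivin) had 150 ± 38.8 CPM against 87.9 and 57.2 CPM, and the checkpoint kinase BUB1 had 66.3 ± 9.29 CPM against 41.2 and 27.6 CPM. Colony 6 moved least in the G2/M list, with a median 0.02 above the parental library without DOX, against 0.27 in colony 4 and 0.50 in colony 8. The parental DOX library stood at -0.22 in the G2/M list and -0.07 in the G1/S list on the same scale, and without the parental library that had no DOX the G2/M median was 0.51. Replication-dependent histones had a median of 0.34 (camera, adjusted p = 0.0199, and 0.641 with an estimated correlation) and -0.33 in the parental DOX library. The histone call ended without that library (median 0.27) and without colony 8 (median 0.26, camera, adjusted p = 0.109). It also ended without genes with shared 3' ends (median 0.36, camera, adjusted p = 0.0839). Without the parental library that had no DOX the histone median was 0.63 (camera, adjusted p = 0.0114).

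Lists of protein synthesis, folding and degradation genes also rose, and each of these calls ended when the parental DOX library, the one with 26.7% mitochondrial counts, was left out. Genes of endoplasmic reticulum chaperones and the unfolded protein response had a median log2 fold change of 0.33 (camera, adjusted p = 0.0052; adjusted p = 0.641 with an estimated correlation), and a median of 0.21 without that library (adjusted p = 0.0639). DERL2, a component of the degradation machinery of the endoplasmic reticulum, had 23.7 ± 3.45 CPM (n = 3) against 10.7 and 7.37 CPM in the parental libraries without and with DOX. Proteasome subunits had a median of 0.22 (camera, adjusted p = 0.0199; adjusted p = 0.641 with an estimated correlation; median 0.07 and adjusted p = 0.891 without that library, adjusted p = 0.0576 without colony 4, and 0.0531 without colony 8 over the genes tested with all 5 libraries). Cytosolic ribosomal proteins had a median of 0.23 (camera, adjusted p = 0.0317; adjusted p = 0.641 with an estimated correlation; median 0.09 and adjusted p = 0.668 without that library, and adjusted p = 0.508 without colony 6). Amino-acid and proline or serine metabolism genes had a median of 0.28 (camera, adjusted p = 0.0384, and 0.471 with an estimated correlation), and of 0.12 without the parental DOX library. The amino-acid call also ended without the parental library that had no DOX, where the median was 0.38, and without colony 6 (camera, adjusted p = 0.136). With a filter of 50 counts in 2 libraries the proteasome, ribosomal protein and amino-acid calls ended (camera, adjusted p = 0.094, 0.138 and 0.0963). Their medians were then 0.17, 0.18 and 0.23. Without genes with shared 3' ends the ribosomal protein and amino-acid calls ended at medians of 0.19 and 0.13 (camera, adjusted p = 0.32 and 0.183). The amino-acid call also ended in the fit with 3 groups, at an unchanged median of 0.28. In the amino-acid list GLUL, glutamine synthetase, had 143 ± 17.96 CPM against 78.0 and 71.4 CPM. Set against the parental library without DOX, the parental DOX library stood at -0.25, -0.56, -0.41 and -0.11 in these 4 lists. Without the parental library that had no DOX, the medians of the chaperone, proteasome and ribosomal protein lists were 0.57, 0.57 and 0.46 (camera, adjusted p = 0.0204, 0.000415 and 0.00109), and without colony 6 those of the ribosomal protein and amino-acid lists were 0.15 and 0.13. Adjusted over the list alone, 0 members of these 4 lists passed with edgeR, while DESeq2 gave DERL2 in the chaperone list and TAT and GLUL in the amino-acid list, all higher, and 0 in the proteasome list. The 1 ribosomal protein gene that DESeq2 called, RPS18, was lower in the colonies (log2 fold change -2.05, adjusted p = 0.0316 over all genes), against the direction of its list.

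Markers of basal epithelium, Notch targets and YAP-TEAD targets fell as lists. The basal and keratinocyte list had a median log2 fold change of -0.70 over 11 tested members (camera, adjusted p = 0.0052; adjusted p = 0.471 with an estimated correlation), and 1 member, TRIM29, passed with edgeR when adjusted over the list alone (with DESeq2 also KRT80, both lower). Over the genes tested with all 5 libraries the median was -0.28 without the parental DOX library (camera, adjusted p = 4.98e-06), and -0.43, -1.23 and -0.44 without colonies 4, 6 and 8. KRT80 had 9.80, 7.54 and 8.62 CPM in colonies 4, 6 and 8 against 43.4 CPM in the parental library without DOX and 6.49 CPM in the parental DOX library, and the call ended without the parental library that had no DOX (median -0.82, adjusted p = 0.376) and with a filter of 50 counts in 2 libraries (-0.58, adjusted p = 0.0594). Notch targets had a median of -0.34 over 10 members (camera, adjusted p = 0.0199; adjusted p = 0.471 with an estimated correlation). HES1, a transcriptional repressor downstream of Notch, had 79.8 ± 35.9 CPM (n = 3) against 195 and 189 CPM, the receptor NOTCH3 had 25.5 ± 1.82 CPM against 42.5 and 46.9 CPM, and both passed with edgeR when adjusted over the list alone, where DESeq2 gave the same 2. The Notch call ended without either parental library, at medians of -0.36 without the DOX library and -0.41 without the other. It also ended without colony 6 (median -0.54, camera, adjusted p = 0.0656). In none of these fits was the shift smaller than with all libraries. YAP-TEAD targets had a median of -0.43, with 11 of 12 members negative (camera, adjusted p = 0.0249; adjusted p = 0.471 with an estimated correlation; median -0.33 and adjusted p = 0.401 without the parental library that had no DOX, over the genes tested with all 5 libraries), and 0 members passed with edgeR or DESeq2 when adjusted over the list alone. Against the parental library without DOX, the parental DOX library stood at -0.47 in the basal list, 0.30 in the Notch list and -0.28 in the YAP-TEAD list.

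**Figure D3:**
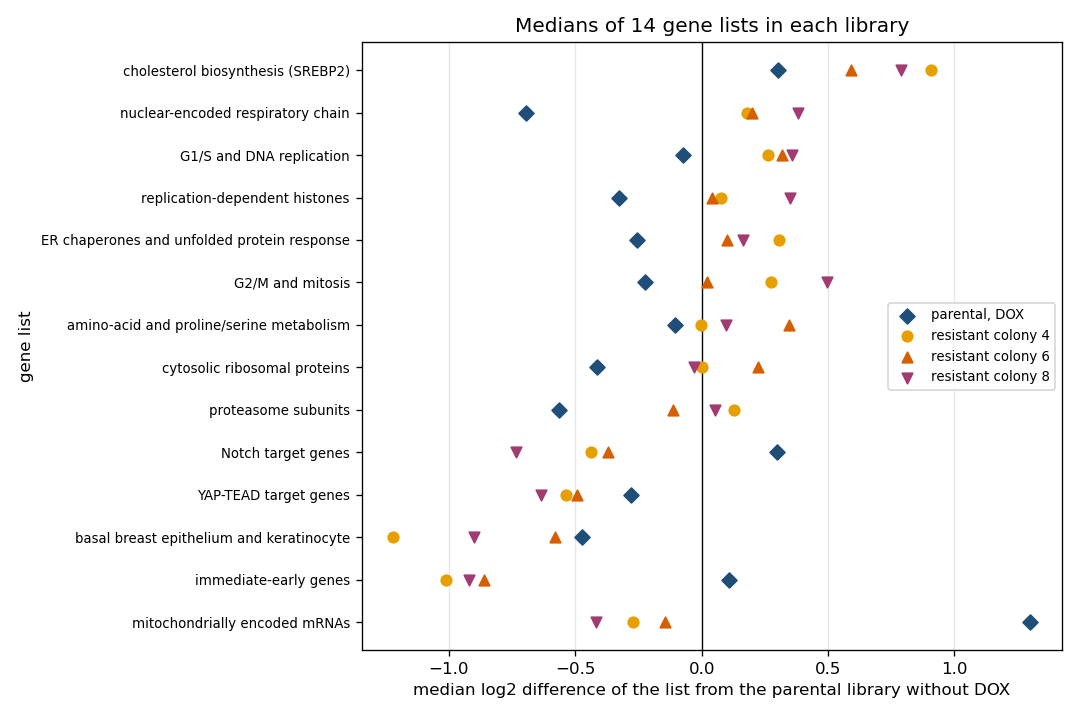
Median log2 difference from the parental library without DOX for the 14 gene lists past the camera threshold, 1 marker per library, with the line at 0 standing for the parental library without DOX. For mitochondrially encoded mRNAs the parental DOX library lies at 1.30 and the colonies from -0.42 to -0.14, while for cholesterol biosynthesis the colonies lie at 0.91, 0.59 and 0.79 and the parental DOX library at 0.30.

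Single members of lists that did not pass as a whole passed with edgeR when adjusted over the list alone. Beside WNK1 these were GDF15 among p53 targets, ANO1 among ion channels, EGR1 among RAS-MAPK output genes, MAP1A among microtubule-associated proteins, OCLN among adhesion genes, ITGA2 and ITGA3 among integrins, and S100A10. With DESeq2 lists without an edgeR call also had members past the threshold over the list alone. These were PIP, TFF3, CLDN3 and UGT2B11 (higher) and TFF1 (lower) in the luminal list, UGT2B28 and UGT2B11 (higher) and ALDH3B2 (lower) in drug metabolism, and ZBTB16 (higher) and PMEPA1 (lower) among androgen receptor targets. ACSL4 and NFKBIA were higher in the SREBP1 and NF-kB lists, and HMOX1, TFF1, IRS1 and PMEPA1 lower in the NRF2, estrogen receptor, PI3K-FOXO and TGF-beta lists. In the adhesion list DESeq2 called CLDN3 and CLDN8, both higher, and in the p53 list also POLH (lower). In the S100 list it also called S100A9 (higher, log2 fold change 1.51) and S100A14 (lower, -0.85). Of these genes added by DESeq2, HMOX1 alone passed over all genes (DESeq2, adjusted p = 0.0367). Adjusting within each list alone does not control errors across the lists. S100A10, an annexin partner, had 24.5 ± 2.45 CPM (n = 3) against 57.0 and 96.5 CPM in the parental libraries without and with DOX. ITGA2, a collagen receptor subunit, had 26.9 ± 1.86 CPM against 101 and 37.2 CPM. MAP1A was sparse, at 1.22, 1.92 and 0.297 CPM in colonies 4, 6 and 8 against 10.3 and 4.56 CPM, and OCLN, the tight junction protein occludin, had 1, 3 and 1 counts in the colonies against 21 and 9 in the parental libraries. UGT2B28 and UGT2B11, which conjugate steroids, differed between the colonies. UGT2B28 had 196 and 251 CPM in colonies 4 and 8, 19.7 CPM in colony 6, and 12.2 and 2.98 CPM in the parental libraries; 58.1% of the words in its 3' end occur in other genes.

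The lists that address the named targets of rigosertib did not pass. Alpha- and beta-tubulins had a median log2 fold change of 0.34 (camera, adjusted p = 0.369), microtubule-associated proteins -0.21 (0.251), kinesins 0.06 (0.597), RAS-MAPK output genes -0.48 (0.182) and PI3K-FOXO output genes 0.02 (0.717). Over the genes tested with all 5 libraries, the RAS-MAPK median without the parental DOX library was -0.73 (camera, adjusted p = 0.000111) and that of microtubule-associated proteins -0.20 (adjusted p = 0.0153). Without the other parental library these medians were 0.14 (adjusted p = 0.985) and -0.05 (adjusted p = 0.985). The list of Polo-like kinases and RAS effectors had a median of -0.07 (camera, adjusted p = 0.842). Of the drug response lists, ABC transporters had a median of -0.08 (camera, adjusted p = 0.399), drug metabolism 0.25 (0.258), NRF2 targets 0.12 (0.353), apoptosis regulators -0.14 (0.49) and p53 targets -0.14 (0.416). Stress and repair lists included heat-shock proteins at 0.25 (camera, adjusted p = 0.176), the ATF4 response at -0.09 (0.344), hypoxia targets at 0.15 (0.182), NFAT5 targets at 0.07 (0.502), DNA repair at 0.04 (0.399) and autophagy and lysosome at -0.06 (0.783). Without the parental library that had no DOX, heat-shock proteins were at 0.81 (camera, adjusted p = 0.00333) and NRF2 targets at 0.45 (adjusted p = 0.0102). Without the parental DOX library both had the opposite sign, at -0.06 (adjusted p = 0.593) and -0.13 (adjusted p = 0.092). Without colony 6, over the genes tested with all 5 libraries, the ATF4 response was at -0.54 (camera, adjusted p = 6.95e-06) and drug metabolism at 0.42 (adjusted p = 0.00018). For the luminal, NRF2, apoptosis, PI3K-FOXO, Polo-like kinase and TGF-beta lists, the median, the mean and the direction given by camera did not all have the same sign.

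Of the lists for lineage and signalling, luminal and apocrine epithelium had a median log2 fold change of -0.06 (camera, adjusted p = 0.182), androgen receptor targets 0.10 (0.466), estrogen receptor targets -0.15 (0.597) and receptor tyrosine kinases -0.38 (0.176). PIP, an apocrine secretory protein, had 219, 70.9 and 293 CPM in colonies 4, 6 and 8 against 64.7 and 64.6 CPM in the parental libraries, and ERBB2 (HER2) had 105 ± 13.6 CPM (n = 3) against 142 and 180 CPM. Mesenchymal genes had a median of -0.65 over 5 members (camera, adjusted p = 0.176), cell adhesion genes -0.43 (0.186), integrins -0.06 (0.361), S100 proteins -0.77 (0.0849), TGF-beta targets 0.04 (0.842), Wnt targets -0.33 (0.361) and NF-kB targets -0.27 (0.669). Type I interferon response genes had a median of 0.15 (camera, adjusted p = 0.182), MHC class I genes 0.26 (0.326), ion channels -0.15 (0.429), glycolysis 0.09 (0.361) and ribosome biogenesis -0.18 (0.182). Over the genes tested with all 5 libraries, 4 of these lists passed with camera without the parental DOX library, namely ribosome biogenesis (-0.51, adjusted p = 5.24e-08), cell adhesion (-0.54, 0.00026), S100 proteins (-1.05, 0.000386) and integrins (-0.25, 0.0102). Without the other parental library none of these 4 passed, and their medians were 0.39 (adjusted p = 0.28), -0.15 (0.835), 0.06 (0.947) and 0.24 (0.985). Of all 35 lists that did not pass, 14 had a median whose sign rested in this way on which parental library was left out. Among them were NF-kB targets (-0.39 without the DOX library, 0.43 without the other), MHC class I genes (-0.12 and 1.02) and mesenchymal genes (-0.57 and 0.04). Without colony 6 S100 proteins passed at -0.86 (camera, adjusted p = 0.0089) and the luminal list at a median of -0.01 with camera's direction higher (adjusted p = 0.0104), and without colony 8 the interferon list passed at 0.35 (adjusted p = 0.000255). Markers of other cell types were too sparse to test as lists. Of the leukocyte markers 1 was tested and none exceeded 26.1 CPM, of the fibroblast and endothelial markers 2 were tested with at most 185 CPM (COL1A1), MHC class II genes stayed at or below 1.23 CPM, and cancer-testis antigens at or below 19.3 CPM.

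The parental library with DOX was set beside the one without it, without rigosertib on either side. DOX itself, Cas9 and editing by the guide library come together here and cannot be told apart. With 1 library on each side, the difference has no replicate check and is given as values of these libraries. The DOX library held more mitochondrially encoded mRNA and less mRNA for ribosome assembly, the respiratory chain, heat-shock proteins and the proteasome. Mitochondrially encoded mRNAs had a median log2 ratio of 1.24 over 13 genes, above all of 10000 random lists of the same size and expression. Ribosome biogenesis and MYC target genes had a median of -0.98 and nuclear-encoded respiratory chain genes a median of -0.76, both below all random lists. Heat-shock proteins stood at -0.78 (percentile 0.23), proteasome subunits at -0.62 (percentile 0.15), NRF2 targets at -0.68 (percentile 0.57) and ribosomal proteins at -0.47 (percentile 0.37). Cholesterol biosynthesis stood at 0.25 (percentile 98.5). Members of a list can move together, unlike those of random lists, so these percentiles do not measure how unusual a median is. Scaling by library size only moved the median of all 7197 genes compared from -0.17 to -0.25 and left the signs of these medians as given. Of these genes 1237 differed by 2-fold or more, 507 higher and 730 lower with DOX.

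Several of the largest ratios came from genes at or near 0 in one of the parental libraries. NPIPA9, of a family of near-identical copies, had 235 counts with DOX and 0 without, at least 87.7-fold higher against a limit of 3 counts. HNRNPR, an RNA-binding protein, had 0 counts with DOX and 298 without, and 238, 201 and 326 in colonies 4, 6 and 8. HMOX2 (heme oxygenase) had 0 counts with DOX and 111 without, and 0, 0 and 2 in these colonies. SQSTM1, the autophagy receptor p62, had 2 counts with DOX and 287 without, but also 0, 61 and 305 in colonies 4, 6 and 8. GGNBP2 had 270.8 CPM with DOX and 4.23 CPM without, and 201, 252 and 211 CPM in the colonies. VPS28, TADA2A and HERC2P2 were higher with DOX (66.3, 28.4 and 22.6 CPM against 0.940 CPM each), and YTHDC1 and SNORD3C were lower (3.69 and 1.23 CPM against 145 and 100.3 CPM). NPIPA9, HERC2P2 and SNORD3C share from 65.6% to 100% of the words in their 3' ends with other genes, so their levels are uncertain.

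Single colonies had genes far outside all other libraries. Colony 8 had 419 CPM of SLC1A7, a glutamate transporter, where the other 4 libraries ran from 20.4 to 62.9 CPM, and 114 CPM of MYBPC1, a myosin-binding protein, where they ran from 4.56 to 17.0 CPM. Colony 8 was lowest in CARS1, a cysteinyl-tRNA synthetase, at 1.04 CPM against at least 10.9 CPM elsewhere, and in OPTN at 1.04 CPM against at least 5.66 CPM. It was also lowest in EIF3C, at 9.66 CPM against at least 98.1 CPM. EIF3CL, which shares 68.2% of the 3' words of EIF3C, had 981 counts in colony 8, where EIF3C had 65. With the counts of both added, the gap fell from 3.3 to 0.319 on the log2 scale, so this contrast may be one of read assignment. Colony 4 had 34.6 CPM of NDUFA6, a complex I subunit, against at most 0.641 CPM elsewhere, and 2.30 CPM of TJP1, the tight junction protein ZO-1, against at least 34.9 CPM. Colony 4 also had 334 CPM of the mitochondrial transfer RNA MT-TS1, which had at most 0.470 CPM in any other library. Colony 6 had 19.2 CPM of NEDD8 against at most 2.23 CPM elsewhere, and less FAM83H (1.12 CPM), NCSTN (1.92 CPM) and RPL7A (1.92 CPM) than any other library. NEDD8, RPL7A and EIF3C share 18.5%, 59.3% and 70.1% of their 3' words with other genes. Exons of NDUFA6, SLC1A7, MYBPC1, CARS1, OPTN, NCSTN, NEDD8 and RPL7A overlap exons of another annotated gene. The strand setting of the counting is not given, so these levels are uncertain. Each of these contrasts sets 1 library against the rest, with no test. The remaining genes named by this rule were XAGE1B in colony 8, RPS26P47 and LINC01881 in colony 6, SNORD3A and 2 unnamed genes in colony 4.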

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

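Leaving out the mitochondrially encoded genes with MALAT1, leaving out genes with shared 3' ends, the list test in the fit with 3 groups, leaving out each library with the genes tested in all 5, DESeq2 on the genes edgeR tested and the test of doxycycline (DOX) in that fit were chosen after seeing the data. The count of genes called by edgeR was 0, with 1029 at an unadjusted p under 0.05. It was 12 without a filter on low counts, 51 with DESeq2, which was run without that filter, 51 with DESeq2 on the genes edgeR tested, 0 with limma-voom, and 0 to 12 when each library was left out in turn, the 12 without the parental DOX library. The count of gene lists past the threshold was 14, and it was 0 with the correlation estimated per list and 1 with fry. Under the other scalings, filters and left-out libraries 10 to 16 lists passed, with 5 higher and 10 lower without the parental DOX library and 10 higher and 2 lower without the other parental library, and both splits were the same over the genes tested with all 5 libraries. The added fit with 3 groups gave 1 gene between the parental libraries, GGNBP2 (edgeR, adjusted p = 0.0111), where 1237 genes differed by 2-fold or more; its spread came only from the 3 colonies, so it compares these 2 libraries and not the treatments. The log2 fold change of PLK1 was -0.17, ranged from -0.41 (without colony 8) to 0.14 when each library was left out, and turned positive without the parental library that had no DOX (edgeR, adjusted p = 0.879; the parental arm then holds 1 library, assumed to vary like the colonies). By construction the list test with an estimated correlation takes its degrees of freedom from the 5 libraries and not from the genes; for the other changes the cause was not tested. No paired analysis was possible because the colonies and the parental libraries share fewer than 2 replicate numbers. With 5 libraries and 3 residual degrees of freedom, the simulated recovery of 2-fold changes by edgeR was 17.9%, so changes of that size were mostly not detectable here. Larger log2 fold changes did not pass either, such as 3.14 for TAT and -2.50 for WNK1 (edgeR, adjusted p = 0.588 and 0.474). The higher simulated recovery of larger changes may therefore not hold for these libraries.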

Other observations

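For WNK1, the comparison with the parental library without DOX alone and the question of guide editing were tests chosen only after the result was seen. So were the doxycycline comparison, the respiratory chain list set against all other genes, the ranks of the splits for single lists and the separate test of shared 3' ends. The genes in the next paragraph were also chosen after their values were seen.

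Several other genes differed between the colonies and the parental libraries by DESeq2 but did not meet the rule for naming genes. That rule asked for an average log2 CPM of at least 3 and all 3 colonies beyond both parental libraries. The size of their fold changes therefore does not rank them above the genes it named. GNAI1, an inhibitory G protein subunit, had a log2 fold change of 4.16 (DESeq2, SE 0.786, adjusted p = 0.000516), and PRKAR2B, a regulatory subunit of protein kinase A, of 4.05 (DESeq2, SE 0.908, adjusted p = 0.00667). SRGAP1, a GTPase-activating protein of the SLIT-ROBO pathway, had -2.74 (DESeq2, SE 0.612, adjusted p = 0.00667). HMOX1, the inducible heme oxygenase and a member of the NRF2 list, had 40.4 CPM in the parental library without DOX and 4.21 CPM in the parental DOX library, against 4.29, 4.17 and 2.97 CPM in colonies 4, 6 and 8. By edgeR 0 of these passed with the usual filter and all 5 libraries, where 1029 genes had an unadjusted p under 0.05, while without a filter GNAI1 had an adjusted p of 0.00887 and SRGAP1 of 0.0276. The parental library without DOX was also alone in its level of KRT16, a stress keratin, with 113 counts against at most 2 in any other library, and of MS4A7, with 317 counts against at most 28.

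WNK1 was lower in the 3 colonies than in both parental libraries. The share of 31-base words in its 3' end that occur in another gene was 0%, which argues against reads shared with another gene. The median log2 fold change of 16 genes within 3 Mb was 0.001 (SE 0.12), with single genes from -1.17 to 0.957. This argues against a loss of most of that region. A loss confined to WNK1 or a few neighbours could leave the median unchanged, so it stays open. Against the parental library without DOX alone WNK1 was at -1.72, with an SE of 0.415 that comes from the colonies alone; the pattern itself fixes this sign, so how much of the difference the DOX library sets stays open. Editing of WNK1 by the guide library may lie behind the lower level, but 0 of the deposited count columns read a guide or an edited allele, so this stays open.

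The parental DOX library stood apart from the parental library without DOX. A few genes taking most of the counts move all other genes by 1 shared factor. Such a factor alone would leave a list at the median of the other genes. The respiratory chain list lay at -0.592 from the median of all genes not encoded in mitochondria, below all of 10000 random lists of the same size and expression. It was picked after it had stood apart in these same libraries, and its members can move together. The percentile therefore decides nothing about such a factor. After a correction on transcript length the mitochondrially encoded mRNAs were at 1.69, further from 0 than before it, which argues against transcript length for that list. The respiratory chain and ribosomal protein lists moved to -0.50 and -0.16 under the same correction, so length could account for part of their shift. An effect of doxycycline, which is known to act on mitochondrial translation, could also give the median of 1.24. It cannot be told apart from a difference between single libraries because 1 library stood on each side. Nor can it be told apart from Cas9 or editing by the guide library.

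Neighbouring genes differed together along some chromosomes. Of 199 stretches of 40 or more genes per library, 12 in colony 4, 3 in colony 6 and 11 in colony 8 lay beyond the 99th percentile of shuffled orders, as did 5 in the parental library without DOX and 2 in the parental DOX library. A change in copy number could give this, and 1 stretch in the colonies also met the size set for it, over 0.5 from the library's median (colony 4, chromosome 11 from 62712630 to 65305589, 0.511), where colony 8 stood at -0.463. The parental DOX library had 2 stretches of that size (chromosome 4 at -0.591 and chromosome 16 at 0.776), so the test does not single out the colonies, and the median differences of expression are no measure of DNA.

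Genes with a gap of 2 or more on the log2 scale between 1 library and the other 4 numbered 62. Their odds ratio of holding a shared 3' end or an overlapping exon was 1.35 (Fisher's exact test, p = 0.302), for a shared 3' end alone it was 3.34 (Fisher's exact test, p = 1.35e-05), and adding the partner's counts brought the gap under 2 in 13 of 26. In 5 of the 13 the partner alone was above the gene in every library, which by itself pulls the gap down. The sum therefore decides nothing for these genes as a set. For the 14 gene lists past the camera threshold, the 10 splits of the 5 libraries into 3 and 2 are too few for a share under 0.05. The real split gave 14 lists, the highest of the others also 14, and 2 splits in all reached that number. The other one, colonies 4 and 8 against the rest, called 20 genes by edgeR where the real split called 0 (51 by DESeq2 and 0 by limma-voom). At an unadjusted p under 0.05 edgeR gave 1029 genes for the real split, 1072 for that one and 1426 for the parental DOX library with colony 6 against the rest. Such splits point to a structure of the samples beside resistance, whose cause was not tested. By limma's camera the real split had the lowest p of the 10 in 9 of the 14 lists. These lists were picked for a low p in that split, which favours this rank, so the 9 are no support for it. The real split ranked 2 for G2/M and for endoplasmic reticulum chaperones, 3 for histones, 5 for the proteasome and 6 for ribosomal proteins. For these lists another split of the libraries gave a lower p by camera.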
